A study of Homo sapiens with 12 samples.

How the data were processed

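Small RNA was sequenced from human CD34-positive adipose stem cells, the stromal progenitor cells of fat tissue that carry the surface protein CD34, kept in endothelial or in basal medium. The 12 libraries formed 6 groups of 2, and each library was placed in its group from its title. Per the labels' protocols, RNA was isolated with a microRNA isolation kit, small-RNA libraries were made with an Ion Total RNA-Seq kit, and sequencing ran on an Ion Proton instrument. CD34-depleted cells, which the protocol names as a further control, were not analysed here. The labels do not say whether 2 libraries of a group came from separate cultures or donors, so p-values measure only the spread between these libraries, which may be technical.

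The authors deposited 1 table of expected counts per library, with 60675 gene rows each, in the format that RSEM writes. Per the submitters' processing notes, STAR, RSEM, bedtools and edgeR were used with genome build hg38. The role, version and order of these tools, the annotation release and the strand setting are not given in the sources used here. An expected count is an estimate that divides reads with several possible origins between genes, so copies of 1 microRNA and overlapping genes share reads. Reads in the row of a long gene include those of any small RNA inside it that has no row of its own or shares its reads.

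The authors also deposited 3 tables of their own comparison of media, 1 per day, whose rows are mature microRNAs. Per the file headers, these hold a log2 fold change, a mean log2 CPM, a p-value and an adjusted p-value. The files do not name the direction of the fold change, the libraries or the test behind it. Values from these tables are named as the authors' wherever they appear.

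Rows of Y-linked genes and of genes of X inactivation, 510 in all, were left out, which left 60165. Of these, 56050 matched the GENCODE 44 annotation of hg38 by gene identifier and 397 more by a symbol found once, together 93.82%. RNA classes, host genes and coordinates came from that annotation. MicroRNA genes were the 1722 rows named as such, of which 1426 matched by identifier and 291 by symbol.

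Expected counts were rounded to whole numbers. Differences were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) in 1 fit of all 12 libraries with 6 groups and 6 residual degrees of freedom, so that every group shared 1 estimate of the spread. Libraries were scaled by TMM, low rows were removed by filterByExpr with a minimum count of 10, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A fit of microRNA genes used their own total as library size and tested 213 genes, which held 99.8% of microRNA counts. A fit of all rows tested 965 genes, which held 99.4% of counts. The biological coefficient of variation was 0.154 in both.

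Media were compared at day 3, 9 and 14. A model with day and medium as terms gave a day-adjusted comparison of 6 against 6 libraries, and an F test of the medium-by-day terms asked whether the effect of medium differed between days. Days 9 and 14 were compared with day 3 within each medium. Standard errors of log2 fold changes were derived from the F statistic. CPM here is the TMM-normalised edgeR value relative to the total of microRNA genes, or of all genes where the fit of all genes is named. Shares of RNA classes were compared by two-sided exact permutation tests over the 924 splits of 6 against 6. Intervals, floors and ratios of low counts cover counting error only. The floor was 3 counts over a group, and intervals had 95% confidence.

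These tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. For each comparison of media, up to 10 microRNA genes higher and 10 lower were named by size of log2 fold change, among those with an adjusted p under 0.05 and a mean count of at least 20 in the higher group. With fewer than 3 in a direction, the 3 of smallest p were given as values. Time comparisons and comparisons of all genes named up to 5 in each direction, the latter leaving out microRNA genes. The 10 most abundant microRNA genes, MIR126, MIR210 and 2 to 4 abundant members of each list were named as well.

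The lists of microRNA genes covered endothelial, mesenchymal and smooth muscle, adipogenic, collagen-regulating (the MIR29 genes), proliferation-suppressing, p53 and senescence, hypoxia (MIR210), blood cell, epithelial and muscle microRNAs, the let-7 family, the MIR17HG cluster with its relatives and the DLK1-DIO3 cluster. The lists of messenger RNAs covered endothelial, stromal, pericyte and smooth muscle, adipocyte, leukocyte, cell cycle, cholesterol synthesis and histone genes. Lists with at least 3 tested members were tested in the day-adjusted comparison with limma's camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2), with fry beside it.

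The procedure was tested on simulated data made from the libraries' own means and sizes, with 40 of 213 microRNA genes or 200 of 965 genes changed in each of 5 runs. For microRNA genes, a 2-fold change was called in 71.9% of cases at day 3, 57.1% at day 9, 73.4% at day 14 and 79.8% in the day-adjusted comparison. A 4-fold change was called in 92.9%, 84.7%, 94.8% and 100% of cases, in the same order. False calls made up 2.44%, 4.14%, 5.29% and 1.12% of calls. In the fit of all genes, 2-fold changes were called in 59.1%, 49.3%, 59.5% and 80.5% of cases. When the stromal messenger RNA list was lowered 2-fold, camera called it in 5 of 5 runs and called 0 other lists. Simulated genes were drawn independently of each other, so these runs could not test camera's preset correlation. All groups shared 1 baseline and changes went up or down with equal chance, so the assumption behind TMM was met by design. Where whole RNA classes shift between libraries, as at day 9, these rates need not hold.

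Alternatives were DESeq2 size factors, no filter, the DESeq2 Wald test (DESeq2 1.42.0), the replicate number as a block, library sizes from all genes, copies of 1 mature microRNA summed, a fit of that day's libraries alone, the mean of the 3 day contrasts, camera with an estimated correlation, other definitions of the microRNA share, and leaving out each library in turn. For the medium-by-day terms a DESeq2 likelihood-ratio test took the place of the Wald test. Thinning to the shallowest library and leaving out the 4 day 9 libraries were added after seeing the data.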

Results

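Small RNA was measured in CD34-positive adipose stem cells, progenitors of fat stroma selected with magnetic beads, in a study of how their microRNAs change as they are driven towards an endothelial fate. Cells were plated at 8000 per cm2 and grown to between 80% and 90% confluence in basal medium with 10% serum. They then stayed in basal medium or moved to endothelial medium, which held 50 ng/ml of VEGF, the main growth factor of blood vessel cells, and 2% serum. VEGF and serum therefore differed together between media. Each medium was sampled at days 3, 9 and 14, with n = 2 libraries per medium and day.

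Libraries held between 321577 and 1971181 counts. At day 3 the totals were 1251684 and 1024247 in endothelial medium and 1036360 and 1014907 in basal medium. The day 9 totals were 830605 and 917862 in endothelial medium, and 321577 and 376619 in basal medium, the shallowest of the 12. At day 14 they were 1961123 and 1971181 in endothelial medium and 1348068 and 911633 in basal medium. MicroRNA genes held between 33350 and 148104 counts per library, so a level of 0 allowed up to 20.7 to 83.6 CPM. Between the 2 libraries of a group, correlations across microRNA genes, which are not independent replicates, ran from 0.972 to 0.987 in 5 groups and were 0.886 in basal medium at day 9. Counts of paired libraries differed by more than sampling noise, with a chi-square per degree of freedom between 5.92 and 12.9, so no pair was 1 library deposited again. Repeated preparations of 1 culture can differ as much, and the labels do not say whether the 2 libraries of a group came from separate cultures.

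MIR222, a microRNA of vascular and stromal cells, took 20.6% of microRNA counts and MIR145, best known from smooth muscle, 13.1%. MIR21 (7.19%), MIR214 (4.26%) and MIR181A1 (2.78%) came next, and with MIR30C1, MIR138-1, MIR221, MIR3074 and MIR23A the 10 most abundant genes held 59.5%. MIR3074 has no host gene in the annotation and lies on the strand opposite AOPEP. As the strand setting is not given, its reads may belong to a gene on the other strand. Other microRNA genes were left out of this lookup, so a microRNA on the other strand would not have been found. Small nucleolar RNAs, which guide the chemical modification of ribosomal RNA, were the most abundant class at days 3 and 14, with group means between 44.6% and 52.7% of counts. At day 9 their share was 27.8% ± 1.49 in endothelial and 14.3% ± 0.628 in basal medium (SD, n = 2). Mitochondrial ribosomal and transfer RNA together held 31.2% ± 0.591 and 30.7% ± 0.452 of counts at day 9, against group means from 8.17% to 11.0% at the other days. All 4 day 9 libraries thus differed in make-up from the other 8, and labels give no batch that would separate day from preparation.

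**Figure D1:**
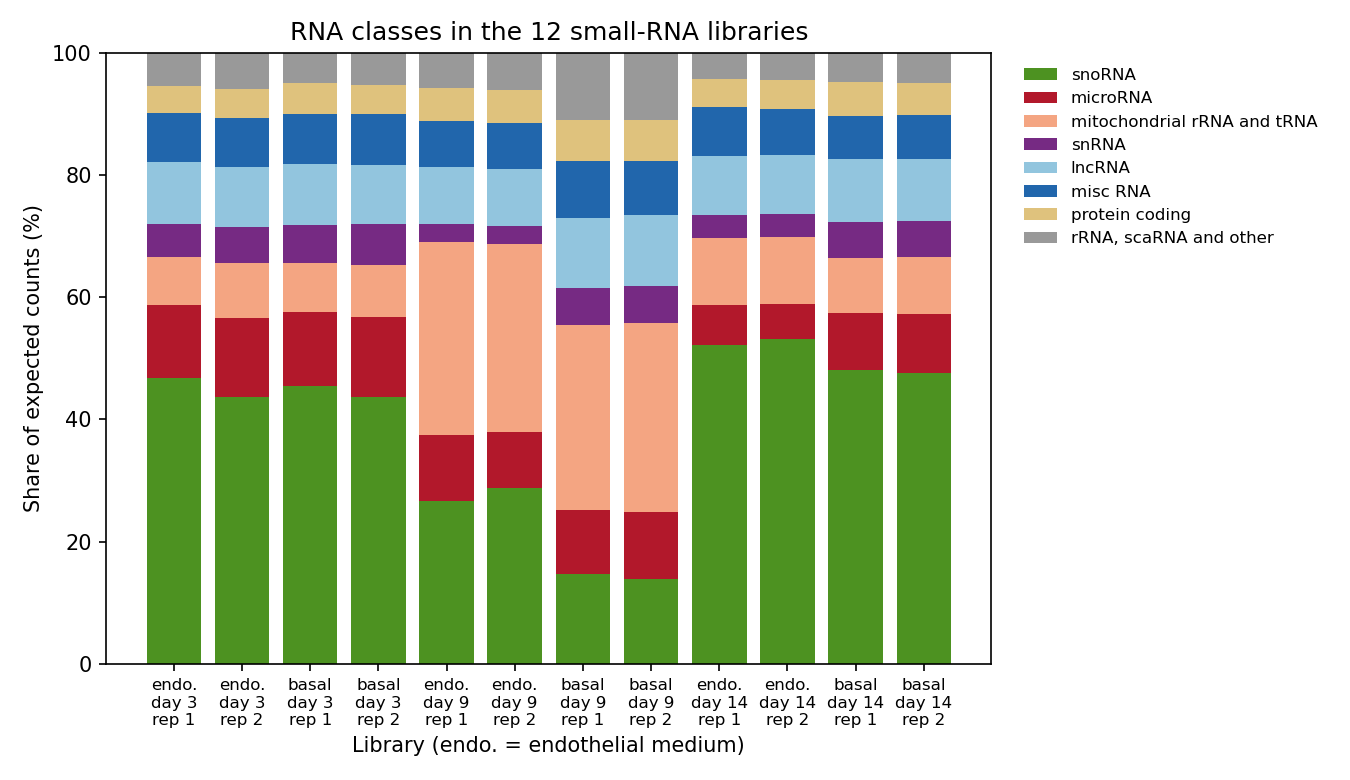
Share of expected counts in each RNA class (percent, stacked bars) in each of the 12 libraries, by medium and day. The snoRNA part is smallest in the basal day 9 libraries, at 14.7% and 13.9%, and the mitochondrial parts are largest at day 9 in both media.

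MicroRNA genes held 9.44% ± 2.89 of counts in endothelial and 10.9% ± 1.48 in basal medium (SD, n = 6), a difference of -1.45 percentage points (exact permutation p = 0.301, adjusted p = 0.554 over 11 classes). Those splits ignore day; over the 216 splits within days, chosen after seeing the data, the exact permutation p was 0.0648. Small nuclear RNAs, the RNA parts of the spliceosome, held 4.06% ± 1.25 in endothelial and 6.14% ± 0.315 in basal medium. Their difference of -2.07 points had an exact permutation p of 0.00216, the smallest that 924 splits can give, and an adjusted p of 0.0238. These splits ignore day as well, and splits within days were not run for this class. By day it held 5.59% against 6.51%, 2.87% against 6.01% and 3.73% against 5.90% (days 3, 9 and 14, endothelial against basal). Long noncoding RNAs differed by -0.850 points with an exact permutation p of 0.0195, which did not pass adjustment (adjusted p = 0.107). By day the microRNA class held 12.3% against 12.6% at day 3, 9.90% against 10.7% at day 9 and 6.10% ± 0.581 against 9.42% ± 0.237 at day 14 (endothelial against basal, SD, n = 2).

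At day 3 the media were close. MIR155, a microRNA induced in inflammatory and vascular activation, stood at 5070 ± 90.5 CPM in endothelial and 7342 ± 721 CPM in basal medium (SD, n = 2), a log2 fold change of -0.53 ± 0.15 (SE). MIR126, which lies in the endothelial gene EGFL7 and is enriched in endothelial cells, stood at 309 ± 10.0 against 166 ± 5.5 CPM. Of the 213 microRNA genes, edgeR called 0, with 18 at an unadjusted p under 0.05, and DESeq2 called 1. MIR155 had an edgeR adjusted p of 0.358, MIR126 of 0.486, MIR31 (-0.41) of 0.473 and MIR145 (-0.28) of 0.486. The 3 higher genes of smallest p were MIR199B (0.83), MIR376A1 (0.56) and MIR199A2 (0.43), as log2 fold changes without a call. MIR3648-2 had 0 counts in endothelial and 10 in basal medium, at least 3.85-fold lower by the floor of 3 counts. Every list fixed beforehand had 0 members called at day 3, also when adjusted over the list alone.

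At day 9 MIRLET7B and MIRLET7C, of the let-7 family that restrains growth and accompanies differentiation, were higher in endothelial medium. MIRLET7B stood at 23971 ± 2683 CPM against 9040 ± 2262 CPM in basal medium (SD, n = 2), a log2 fold change of 1.40 ± 0.16 (SE; edgeR adjusted p = 3.34e-05). MIRLET7C stood at 567 ± 290 against 77.5 ± 30.7 CPM (2.84 ± 0.55, edgeR adjusted p = 0.00219). Its basal level rests on 2 and 4 counts, against 29 and 66 in endothelial medium, so the size of this change is uncertain. MIR195 (2.01 ± 0.51) and MIR16-2 (1.17 ± 0.21), which repress cell cycle genes, were higher as well. On the lower side stood MIR143, a smooth muscle microRNA, at 6696 ± 699 against 14054 ± 11.8 CPM (-1.07 ± 0.14, edgeR adjusted p = 6.77e-05).

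The test called 41 of 213 microRNA genes at day 9, 27 higher and 14 lower, with 63 at an unadjusted p under 0.05. MIR138-2 stood at 5012 ± 359 against 11590 ± 901 CPM (-1.21 ± 0.15, edgeR adjusted p = 4.48e-05) and MIR671 at 6012 ± 1045 against 13925 ± 2509 CPM (-1.21 ± 0.16, edgeR adjusted p = 6.84e-05). MIR193A, a regulator of adipocyte differentiation, was lower at -1.46 ± 0.27 and MIR574 at -1.38 ± 0.23 (edgeR adjusted p of 0.00156 and 6.1e-04). MIR127 (-0.89), MIR138-1 (-0.81), MIR452 (-0.76), MIR19B2 (-0.72) and MIR339 (-0.67) completed the 10 lower genes named by the rule. The higher side also held MIR1301 (2.30), MIR181D (2.12), MIR3618 (1.40), MIR196A2 (1.33) and MIR10A (1.24), the last a microRNA of the HOXB cluster. MIR190A had 41 counts against 2, a ratio of 9.43 with a 95% counting interval from 2.45 to 80.5. Among the most abundant genes MIR222 (0.48 ± 0.13) and MIR21 (0.46 ± 0.15) were higher and MIR145 (-0.39 ± 0.11) lower. MIR126, at 187 ± 0.1 against 63.5 ± 50.4 CPM, did not pass (1.50 ± 0.68, edgeR adjusted p = 0.145), nor did the hypoxia-induced MIR210 (-0.48, edgeR adjusted p = 0.068).

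With library sizes taken from all genes, 47 microRNA genes were higher and 6 lower at day 9, and the median of the 213 moved from 0.09 to 0.42. MIR145 then stood at -0.06 with no call, and it was also lost without basal day 9 replicate 1 (-0.37) or replicate 2 (-0.35). MIR452 lost its call in 14 of 19 alternative settings, MIR196A2 and MIR339 in 8 and MIR181D in 6. Without endothelial day 9 replicate 2 the count was 22.

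By lists at day 9, the 12 let-7 genes had 3 called higher and 1 lower (4 and 1 adjusted over the list alone), with a median log2 fold change of 0.50. The lower one was MIRLET7A3 (-0.55). For that day the authors' deposited table gave -1.37 for let-7a-3p but 0.85 for let-7a-5p. The MIRLET7A3 value therefore does not stand for mature let-7a as a whole. The 8 proliferation-suppressing genes had 4 higher and 0 lower (4 and 0 adjusted over the list alone): MIR195, MIR16-2, MIR15A (0.89) and MIR16-1 (0.77), the last losing its call in 4 of 19 alternative settings, while MIR497, MIR15B, MIR503 and MIR424 were not called. From day 3 to day 9 this list had a median of -0.87 in basal and -0.29 in endothelial medium, so its contrast at day 9 rests on a lower level in the basal day 9 libraries, which stood apart in RNA make-up and depth. The 24 tested endothelial microRNAs had 4 higher and 0 lower (the same adjusted over the list alone) and a median of 0.05. The 17 tested mesenchymal and smooth muscle genes had 3 higher and 4 lower (4 and 4 adjusted over the list alone). The 21 adipogenic genes also split, with 4 higher and 3 lower (the same adjusted over the list alone). In the p53 and senescence list 1 of 4 was called, MIR34A (0.56), a p53 target. The 11 tested genes of the MIR17HG cluster and its relatives had 0 higher and 1 lower, and the 26 of the DLK1-DIO3 cluster 0 higher and 1 lower, MIR127; the counts of these 3 lists were the same adjusted over the list alone.

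By day 14 the smooth muscle pair MIR143 and MIR145 and the inflammatory MIR155 were lower in endothelial medium. MIR143 stood at 8364 ± 21.0 CPM against 23768 ± 1399 CPM in basal medium (SD, n = 2; -1.51 ± 0.14, edgeR adjusted p = 1.29e-06). MIR145 stood at 71704 ± 5593 against 162619 ± 10096 CPM (-1.18 ± 0.11, edgeR adjusted p = 1.29e-06) and MIR155 at 2484 ± 144 against 6545 ± 335 CPM (-1.40 ± 0.16, edgeR adjusted p = 7.77e-06). The endothelial MIR126 was higher, with 36 counts against 2, a ratio of 13.2 with a 95% counting interval from 3.39 to 113 (edgeR adjusted p = 0.00362). Its level was 129 ± 3.17 CPM in endothelial medium at day 14, below the 309 ± 10.0 CPM of day 3.

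Also higher was MIR204, which favours adipogenic over bone differentiation of stromal cells, at 340 ± 37.4 against 35.5 ± 33.9 CPM (3.10 ± 0.59, edgeR adjusted p = 0.00192). MIR335, from an intron of the imprinted gene MEST, stood at 531 ± 135 against 132 ± 42.5 CPM (2.03 ± 0.37, edgeR adjusted p = 0.00117). MIR99A (1.28), MIR502 (1.25), MIR500B (1.21), MIR362 (1.12) and MIRLET7C (1.01) followed, of which MIR500B, MIR502 and MIR362 share an intron of CLCN5. MIR423 and MIR3184 occupy the same bases on opposite strands and had the same value (0.90), so their reads cannot be told apart. MIR20A, of the proliferation-promoting cluster in MIR17HG, was lower at 1208 ± 0.63 against 2541 ± 204 CPM (-1.07 ± 0.16, edgeR adjusted p = 1.43e-04), as was MIR17 of the same cluster at -0.89 ± 0.17. MIR30B (-1.53 ± 0.22, edgeR adjusted p = 1.43e-04), MIRLET7A2 (-0.96), MIR24-2 (-0.87), MIR708 (-0.82) and MIR31 (-0.72) were also lower. For day 14 the authors' deposited table gave -1.07 for let-7a-2-3p but -0.24 for let-7a-5p. The MIRLET7A2 value therefore does not stand for mature let-7a as a whole. MIR365A (-1.45, edgeR adjusted p = 0.0488) lost its call in 14 of 20 alternative settings, MIR138-1 and MIR21 in 7 and MIRLET7C in 5. MIR181A1 (0.79) was higher, MIR23A (-0.68), MIR138-1 (-0.52) and MIR21 (-0.47) lower, and MIR210 did not pass (-0.26, edgeR adjusted p = 0.368).

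The test called 37 of 213 microRNA genes at day 14, 17 higher and 20 lower, with 57 at an unadjusted p under 0.05. DESeq2 size factors gave 25 higher and 19 lower, and library sizes from all genes 7 and 39, with the median of the 213 moving from -0.02 to -0.30. The count was 20 without basal day 14 replicate 1 and 23 without endothelial day 14 replicate 1.

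**Figure D2:**
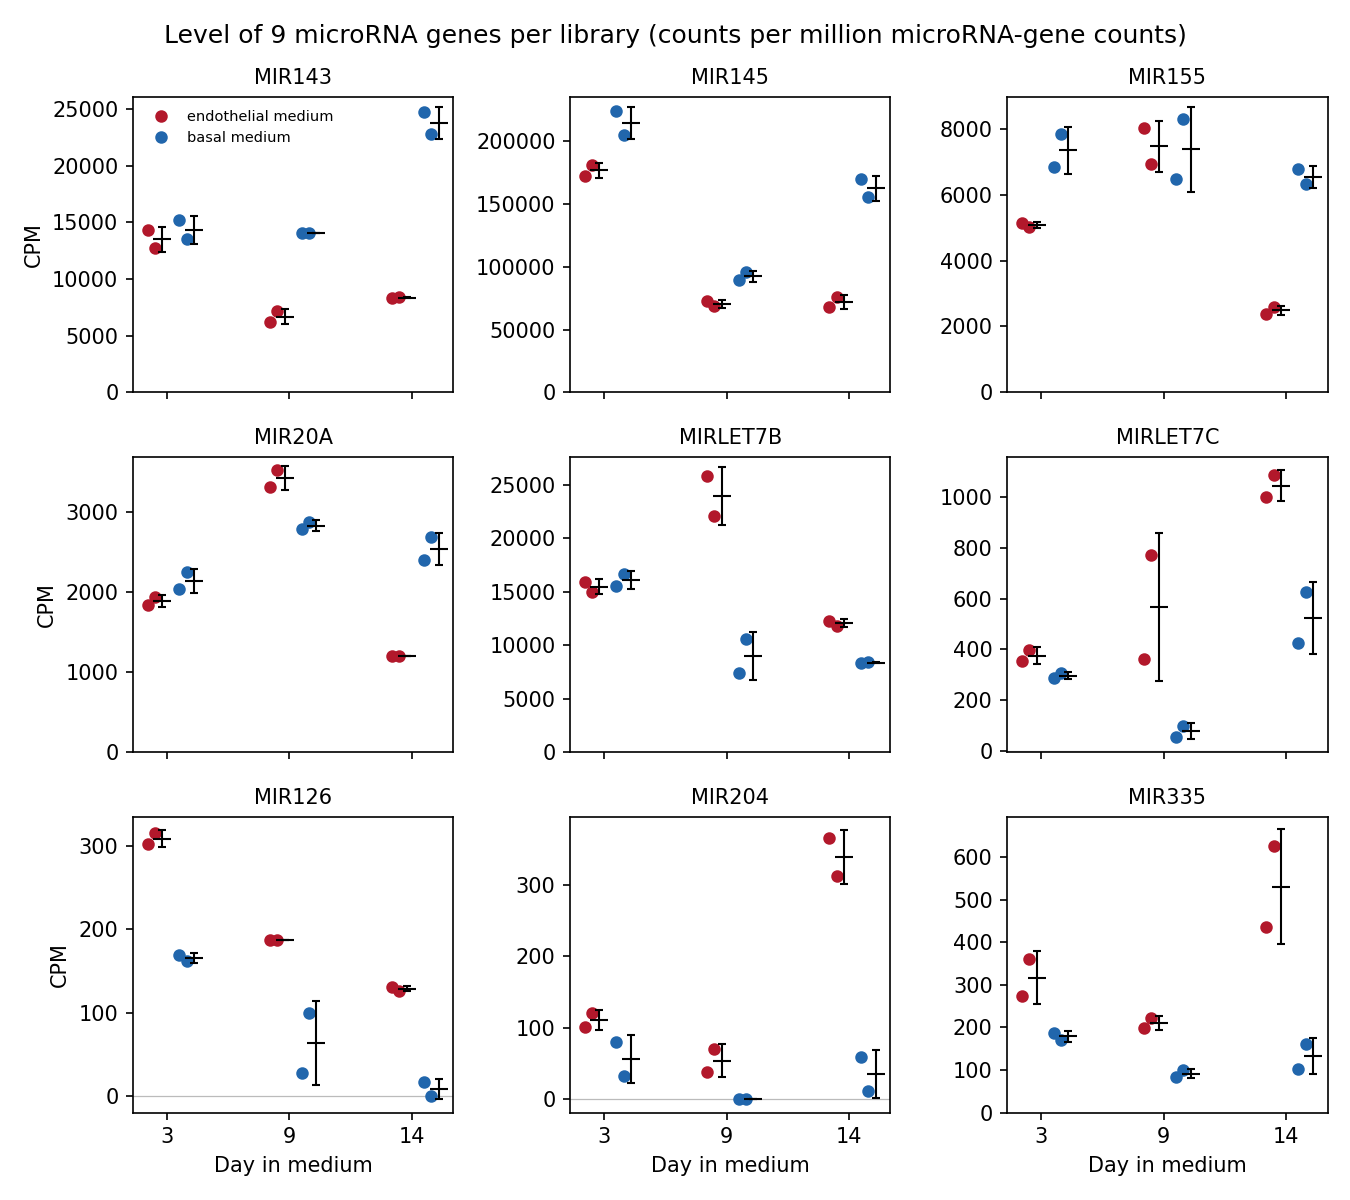
Level of 9 microRNA genes (CPM within microRNA genes, TMM-normalised, linear axes) by day and medium; points are libraries, and the dash and bar are the mean and SD of n = 2. MIR143, MIR145, MIR155 and MIR20A are lower and MIR126, MIR204 and MIR335 higher in endothelial medium at day 14.

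By lists at day 14, the 24 endothelial microRNAs had 2 called higher and 5 lower (the same adjusted over the list alone), with a median of -0.11. Beside MIR126, that list holds MIR155, MIR31, MIR23A and MIR24-2, which were lower. The 11 genes of the MIR17HG cluster and its relatives had 0 higher and 3 lower, with a median of -0.35 (0 and 3 adjusted over the list alone). Mesenchymal and smooth muscle genes again split, with 3 higher and 5 lower of 17 (the same adjusted over the list alone). The let-7 genes had 2 higher and 1 lower and the adipogenic genes 2 and 2, each the same adjusted over the list alone. The lists of proliferation suppressors, p53 and senescence, MIR29 and DLK1-DIO3 genes had 0 called at day 14 (edgeR), also adjusted over the list alone.

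The effects at days 9 and 14 overlapped in part. Lower on both days were MIR138-1, MIR138-2, MIR143, MIR145, MIR19B2 and MIR671, 6 genes where 1.31 would be shared by independent lists (one-sided Fisher's exact p = 5.95e-04). Higher on both were MIR152, MIR218-1, MIR362, MIRLET7B and MIRLET7C, 5 genes against 2.15 (one-sided Fisher's exact p = 0.0471). Fisher's test counts genes as independent. MIR138-1 and MIR138-2 give the same mature microRNA and MIR143 and MIR145 share a host gene, so both p-values only describe the overlap. MIR21 was higher at day 9 and lower at day 14. The log2 fold changes of the 2 days correlated across genes, which are not independent replicates, with r = 0.359; the 2 comparisons share no library.

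**Figure D3:**
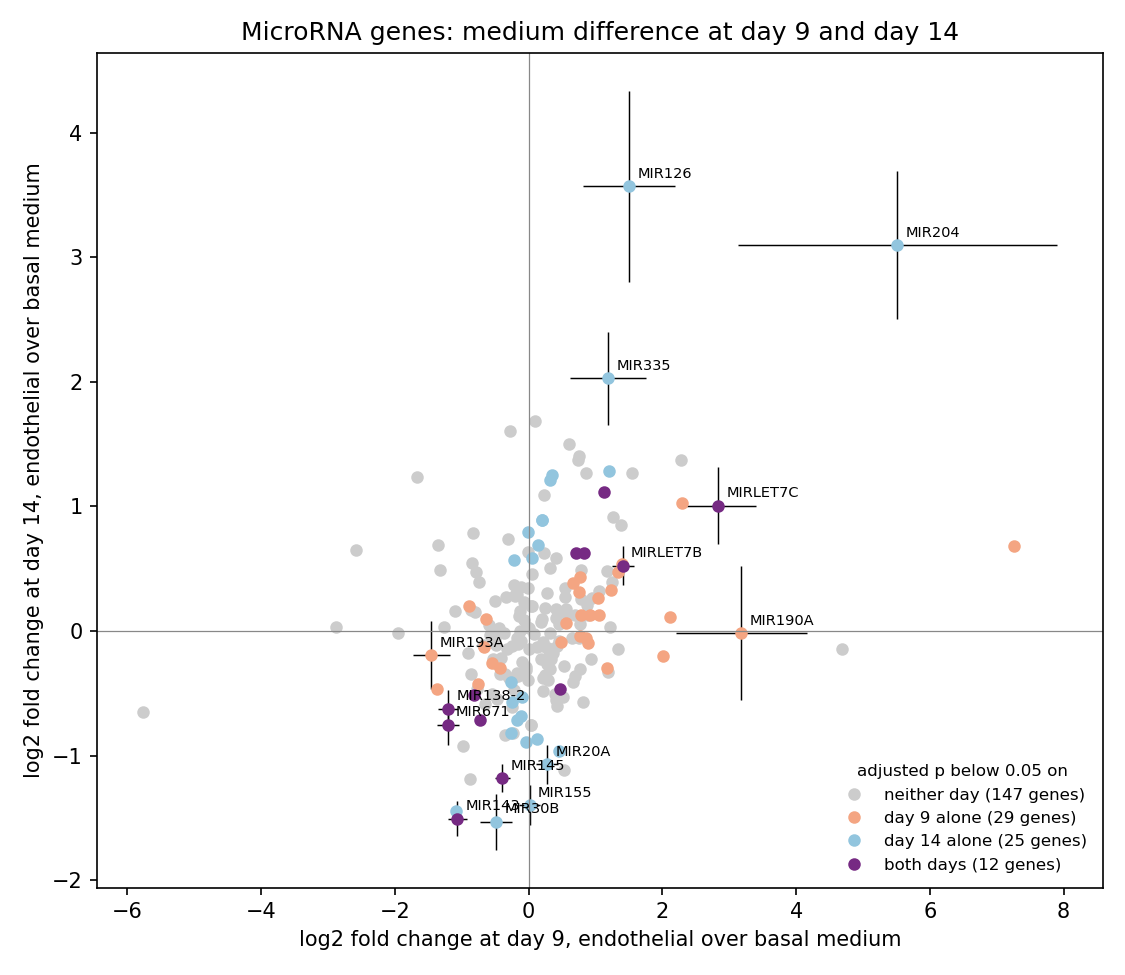
Log2 fold change between media at day 9 (horizontal) and day 14 (vertical) for 213 microRNA genes, coloured by the days on which they were called (12 on both, 29 at day 9 alone, 25 at day 14 alone, 147 on neither), with SE bars on labelled genes. MIR143 lies low on both days, while MIR155 and MIR20A are low at day 14 alone; MIR204 had 0 counts in basal medium at day 9, so its horizontal place is no bound.

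Over the 3 days together, MIR204 (2.17 ± 0.46), MIR126 (1.49 ± 0.36) and MIR335 (1.37 ± 0.26) were higher in endothelial medium, with edgeR adjusted p of 0.00631, 0.012 and 0.0052. MIR143 (-0.89 ± 0.18, edgeR adjusted p = 0.00605) and MIR145 (-0.62 ± 0.14, edgeR adjusted p = 0.00631) were lower, as were MIR138-2 (-0.72 ± 0.13) and MIR671 (-0.69 ± 0.16). MIR1301 (1.16), MIRLET7C (1.04), MIR99A (1.00), MIR362 (0.84), MIRLET7B (0.61), MIR500B (0.60) and MIR199B (0.57) were higher. The day-adjusted test called 36 genes, 18 higher and 18 lower, with 59 at an unadjusted p under 0.05. MIR365A (-0.98), MIR455 (-0.73), MIR30B (-0.67), MIR193A (-0.65) and MIR574 (-0.60) were lower too, but lost their calls in 7 to 13 of 20 alternative settings. MIR155 (-0.64 ± 0.18, edgeR adjusted p = 0.0219) lost its call without endothelial day 14 replicate 1 (-0.45) or 2 (-0.49) or basal day 14 replicate 1 (-0.50).

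With library sizes from all genes the split was 10 higher and 4 lower. The count was 18 without endothelial day 14 replicate 2 and also 18 without basal day 14 replicate 1. Leaving out the 4 day 9 libraries gave 28 genes, of which 21 were among the 36, and MIRLET7B then stood at 0.24 with no call. MIR210 stood at -0.28 (edgeR adjusted p = 0.146), so the hypoxia list, which holds this gene alone, had 0 called. Adjustment over a list of 1 gene corrects nothing, and MIR210 was under 0.05 only unadjusted.

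Whether the effect of medium changed with time was tested by the medium-by-day terms, which passed for 15 of 213 microRNA genes. MIR143 had the smallest adjusted p (edgeR, 0.00104), with mean levels of 13522, 6696 and 8364 CPM at days 3, 9 and 14 in endothelial medium and 14374, 14054 and 23768 CPM in basal medium. MIRLET7B, MIR155, MIR20A and MIR145 each had an edgeR adjusted p of 0.00224. MIR155 levels were 5070, 7466 and 2484 CPM in endothelial and 7342, 7375 and 6545 CPM in basal medium. MIR20A levels were 1891, 3425 and 1208 CPM against 2143, 2832 and 2541 CPM. The count was 9 without endothelial day 9 replicate 1 and 28 without basal day 9 replicate 2.

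In basal medium, day 9 differed from day 3 in 40 microRNA genes, 19 higher and 21 lower. MIR671 (2.09 ± 0.17, edgeR adjusted p = 1.84e-07), the erythroid MIR451A (1.93), MIR29B2 (1.59), MIR193A (1.56) and MIR186 (1.29) were higher. MIR543 (-2.20), MIRLET7C (-1.90), MIR503 (-1.52 ± 0.16, edgeR adjusted p = 2.83e-06), MIR196A2 (-1.44) and MIR146B (-1.42) were lower. In endothelial medium 44 genes differed, 26 higher and 18 lower, led by MIR29B1 (2.16 ± 0.22, edgeR adjusted p = 2.39e-06), a repressor of collagens. MIR451A (2.02), MIR3619 (1.80), MIR7-1 (1.72) and MIR29B2 (1.53) were also higher, and MIR181A2 (-2.40), MIR145 (-1.33 ± 0.11), MIR503 (-1.32), MIR424 (-1.18) and MIR224 (-1.15) lower. Both media shared 11 of the higher genes against 2.32 by independent lists (one-sided Fisher's exact p = 4.18e-07) and 9 of the lower against 1.77 (4.15e-06). Related genes such as MIR29A, MIR29B1 and MIR29B2 were among the 11. Genes are thus not independent, and these p-values only describe the overlap.

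By lists, 3 of 4 MIR29 genes were higher at day 9 than at day 3 in each medium, with medians of 0.86 in basal and 1.24 in endothelial medium. Both tested blood cell microRNAs, MIR451A and MIR223, were higher at day 9 in each medium. Proliferation suppressors had 0 higher and 4 lower in basal medium (0 and 6 adjusted over the list alone). Endothelial microRNAs had 1 higher and 7 lower in basal (1 and 8 adjusted over the list alone) and 3 higher and 7 lower in endothelial medium (4 and 8 adjusted over the list alone). With library sizes from all genes the splits at day 9 were 9 higher and 57 lower in basal medium, its median moving from -0.04 to -0.44, and 21 and 27 in endothelial medium (0.11 to -0.04). The endothelial count was 28 without endothelial day 3 replicate 1 or endothelial day 9 replicate 2. These comparisons set the day 9 libraries, with their lower share of small nucleolar RNA, against those of day 3.

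By day 14 basal medium differed from day 3 in 11 microRNA genes, 4 higher and 7 lower. MIR671 (0.92), MIRLET7A2 (0.74), MIR143 (0.73 ± 0.14, edgeR adjusted p = 0.00294) and MIR708 (0.54) were higher. MIR181A1 (-1.20), MIR149 (-1.02), MIRLET7B (-0.94 ± 0.16, edgeR adjusted p = 0.00256), MIR424 (-0.91) and MIR320A (-0.88) were lower. MIR126 had 2 counts at day 14 against 39 at day 3 in basal medium, a ratio of 0.0592 with a 95% counting interval from 0.00692 to 0.229. Endothelial medium differed in 19 genes, 5 higher and 14 lower. MIR204 (1.61), MIRLET7C (1.47), MIR218-1 (0.97), MIR146B (0.79) and MIR887 (0.72) were higher. MIR30B (-1.56 ± 0.22, edgeR adjusted p = 1.66e-04), MIR424 (-1.45), MIR145 (-1.30 ± 0.11, edgeR adjusted p = 6.40e-07), MIR155 (-1.03) and MIR503 (-0.83) were lower, and the endothelial list had 2 higher and 6 lower (2 and 8 adjusted over the list alone). MIR145, MIR149, MIR181A1, MIR320A and MIR424 were lower in both media, 5 genes against 0.46 by independent lists (one-sided Fisher's exact p = 1.12e-05). Genes are not independent draws, so this p-value too only describes the overlap.

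With library sizes from all genes the day 14 splits were 2 higher and 15 lower in basal medium (median from -0.05 to -0.26) and 1 and 79 in endothelial medium, where the median moved from -0.01 to -0.58; DESeq2 size factors gave 9 and 13 in endothelial medium. The basal count was 5 without basal day 14 replicate 1 and 6 without either basal day 3 library; the endothelial count was 9 or 11 without endothelial day 14 replicate 1 or 2, 11 without endothelial day 3 replicate 1 and 31 without basal day 9 replicate 2.

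Among all 965 genes at day 9, most called small nucleolar RNAs were higher and most called small nuclear RNAs lower in endothelial medium. Of 279 small nucleolar RNA genes 158 were higher and 20 lower, with a median log2 fold change of 1.07, and SNORD5 stood at 4033 ± 615 against 431 ± 27.3 CPM of all genes (SD, n = 2; 3.23 ± 0.13, edgeR adjusted p = 2.8e-08). Of 55 small nuclear RNA genes 1 was higher and 25 lower, with a median of -0.90. FN1, the matrix protein fibronectin, was lower at 61.4 ± 29.0 against 231 ± 12.4 CPM (-1.91 ± 0.29, edgeR adjusted p = 3.06e-04). The other higher genes named were LINC00623 (5.24 ± 0.45, edgeR adjusted p = 3.29e-06), SNORD45B (3.16), SNORD58A (3.09) and SCARNA16 (3.05), and the lower ones RNA5SP207 (-4.34), U8 (-3.90), RNU2-8P (-3.23), SNORA5C (-3.07) and 1 copy of U1 (-3.91 ± 1.14). That U1 copy had 0 and 36 counts in the endothelial and 234 and 66 in the basal libraries. It lost its call with DESeq2 (-4.29) and without endothelial day 9 replicate 1 (-2.91) or basal day 9 replicate 1 (-2.51), and it stood at -4.58 without basal day 9 replicate 2. Without endothelial day 9 replicate 2 the fit gave -11.55. The 0 counts of the remaining endothelial library set that value, so it is no measured fold. Summed copies gave log2 ratios of -1.38 for U1 and -1.34 for U4, with U2 lower too at 4500 ± 375 against 9028 ± 76.6 CPM, but -0.00 for U5, the most abundant of the 5 families, and 0.23 for U6. The test called 425 genes, 305 higher and 120 lower. DESeq2 size factors gave 226 and 177, with the median of all genes moving from 0.39 to 0.07, and the share of small nucleolar RNA in the basal day 9 libraries, 14.3% ± 0.628, was the lowest of the 6 groups.

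At day 14 small nuclear RNAs were again lower, 26 of 55 genes with 0 higher and a median of -0.95. RNVU1-7, a copy of the U1 RNA that marks the start of introns, stood at 526 ± 41.3 against 1699 ± 30.8 CPM (SD, n = 2; -1.69 ± 0.13, edgeR adjusted p = 2.06e-05). RNU5F-1 (-1.82), RNU5E-6P (-1.71), RNA5SP199 (-1.68) and RNU2-8P (-1.66) were lower too; copies of these RNAs are nearly identical, so counts of single copies are uncertain. COL1A1, the main fibrillar collagen of stroma, stood at 444 ± 34.6 against 1008 ± 12.9 CPM (-1.18 ± 0.15, edgeR adjusted p = 3.25e-04). Higher were RPL13 (2.13), SNORD68 (1.79), which lies within RPL13, RBMX (1.74 ± 0.14, edgeR adjusted p = 2.29e-05), SNORD54 (1.61) and SNORD33 (1.53). Reads in the rows of RPL13 and RBMX may be those of small RNAs inside these genes. Their values need not describe the messenger RNAs. The test called 206 genes, 101 higher and 105 lower, and DESeq2 size factors gave 147 and 81, with the median of all genes moving from -0.05 to 0.06. The count was 113 and 133 without endothelial day 14 replicate 2 and 1, and 121 without basal day 14 replicate 2.

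At day 3 edgeR called 2 of 965 genes, with 116 at an unadjusted p under 0.05, and DESeq2 called 37. TMC5 was lower (-0.74 ± 0.10, edgeR adjusted p = 0.0216) and RP5-875O13.1 higher (0.47 ± 0.07, edgeR adjusted p = 0.03), where reads in either row may be those of small RNAs inside the gene. These calls were not kept in full: 0 genes passed without endothelial day 3 replicate 1, basal day 3 replicate 2 or either basal day 14 library, 1 without endothelial day 3 replicate 2 or either basal day 9 library, and 4 without basal day 3 replicate 1.

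Over the 3 days together the test called 94 of 965 genes, 54 higher and 40 lower. All 19 small nuclear RNA genes called were lower, RNU2-8P (-2.17 ± 0.33) and RNU4-1 (-1.27 ± 0.19) among them, each with an edgeR adjusted p of 0.00503, and RNU2-6P (-1.11), RNA5SP486 (-1.40) and RNA5SP199 (-1.18) were lower as well. Higher were RPL13 (1.48), SNORD54 (1.26), snoU2-30 (1.14), SNORD70 (1.14) and SNORD33 (1.12), and of the small nucleolar RNA genes 32 were higher and 5 lower. The count of 94 was 16 to 18 without basal day 14 replicate 2 or either endothelial day 14 library, 25 to 31 without any 1 of the day 9 libraries, 60 without basal day 14 replicate 1 and 160 without basal day 3 replicate 2.

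The stromal messenger RNA list, mostly matrix genes, leaned lower in endothelial medium. Its 9 tested members of 21 had 2 called lower at day 9 (median -1.61), 1 at day 14 (median -0.61) and 0 in the day-adjusted test (median -0.61), the same numbers adjusted over the list alone. Day-adjusted values were -0.61 for COL1A2, -0.46 for COL3A1, -0.45 for COL1A1 and -0.74 for FN1, none of them called. COL1A1, the most abundant of these 4, stood at 403 ± 20.4 against 405 ± 64.3 CPM at day 9 (SD, n = 2), a log2 fold change of -0.01 ± 0.16 (SE, edgeR adjusted p = 0.970). In this scaling its day-adjusted value thus averages unlike days. Before TMM scaling, its day 9 counts were 316 of 830605 and 304 of 917862 in endothelial medium. In basal medium they were 147 of 321577 and 219 of 376619, a higher share, so the day 9 value depends on scaling. The list was the single one of 10 that camera called, downwards, with an adjusted p of 6.91e-04, and fry gave an adjusted p of 0.0164. The call was lost with no filter (adjusted p = 0.190), with an estimated correlation (adjusted p = 0.226) and without the 4 day 9 libraries (adjusted p = 0.0872).

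The other lists did not pass camera in the day-adjusted comparison. Let-7 genes leaned up (adjusted p = 0.464; 2 called higher and 0 lower, the same adjusted over the list alone) and the MIR17HG cluster and its relatives down (adjusted p = 0.506; 0 and 1, the same adjusted over the list alone). The adipogenic list (3 higher and 3 lower, the same adjusted over the list alone) had an adjusted p of 0.694. Endothelial microRNAs (3 higher and 3 lower, or 4 and 3 adjusted over the list alone), mesenchymal and smooth muscle microRNAs (2 and 4, the same adjusted over the list alone), the DLK1-DIO3 cluster and the proliferation suppressors (0 called, edgeR) each had an adjusted p of 0.639. The endothelial list had a median of -0.02 and a mean of 0.02. The p53 and senescence list (adjusted p = 0.880) and the MIR29 list (adjusted p = 0.944) had 0 called; the latter had a camera direction of up, with a mean of 0.14 and a median of -0.03 in the log2 CPM it used.

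Among lists too small for that test, 1 of 2 blood cell genes was lower, MIR223 (-0.50). The 2 tested pericyte and smooth muscle messenger RNAs, PDGFRB (0.31) and CALD1 (0.42), did not pass. The 1 tested cell cycle gene, CCND1 (-1.23, edgeR adjusted p = 0.0924), did not pass either. With 1 tested gene, adjustment over the list alone corrects nothing, so it was under 0.05 only unadjusted. Its values rest on 1 to 8 counts per library. Lists with 0 tested members were those of other cell types and of sparse transcripts: adipocyte (0 to 5 counts per library), endothelial messenger RNA (0 to 5), leukocyte (0 to 4), epithelial microRNA (0 to 4), muscle microRNA (0 to 2), histone (1 to 17) and cholesterol synthesis genes (0 to 22). Endothelial messenger RNAs such as PECAM1 and KDR were thus not measurable at this depth in these small-RNA libraries.

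In hg38, MIR143 lies on chromosome 5 from 149428918 to 149429023 and MIR145 from 149430646 to 149430733, both on the + strand, in an exon and an intron of CARMN. MIR126 lies on chromosome 9 from 136670602 to 136670686 (+, EGFL7 intron) and MIR204 on chromosome 9 from 70809975 to 70810084 (-, TRPM3 intron). MIR155 lies on chromosome 21 from 25573980 to 25574044 (+, exon of MIR155HG), and MIR20A on chromosome 13 from 91351065 to 91351135 (+, exon of MIR17HG). MIR335 lies on chromosome 7 from 130496111 to 130496204 (+, MEST intron), with an unnamed gene on the other strand whose reads cannot be told apart from it. MIRLET7B lies on chromosome 22 from 46113686 to 46113768 (+, exon of MIRLET7BHG), and MIRLET7C on chromosome 21 from 16539828 to 16539911 (+, exon of MIR99AHG). MIR671 lies on chromosome 7 from 151238421 to 151238538 (+, exon of CHPF2). MIR138-1, on chromosome 3 from 44114212 to 44114310 (+), and MIR138-2, on chromosome 16 from 56858518 to 56858601 (+), give the same mature microRNA, so the division of reads between them is uncertain. MIR30B lies on chromosome 8 from 134800520 to 134800607 (-, intron of an unnamed noncoding RNA). COL1A1 spans 50184101 to 50201632 on chromosome 17 (-) and FN1 215360440 to 215436073 on chromosome 2 (-).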

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

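The 100 drawn splits of the libraries and the test of depth by thinning were set before their results were seen; the other tests of explanations in this part, and the 4 splits that keep groups together, were chosen after the results were seen. The medium-by-day terms, fixed beforehand, singled out genes whose response to medium differed between days.

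Among microRNA genes 15 of 213 had a medium effect that differed between days (edgeR F test). Adjusted p was 0.00104 for MIR143, 0.00224 each for MIRLET7B, MIR155, MIR20A and MIR145, and 0.00412 each for MIRLET7A2 and MIR16-2. It was 0.0128 for MIR30B, 0.0164 for MIR671, 0.0234 for MIR127, 0.0278 for MIR21, 0.0298 for MIR574, 0.033 for MIR222 and 0.0357 for MIR138-2. The remaining gene, MIR301A, had 0.00568 and was higher by 0.92 at day 9. MIR155 and MIR20A were lower in endothelial medium at day 14 and not called at day 9, and MIRLET7B was higher by 1.40 at day 9 and by 0.52 at day 14 on the log2 scale.

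In the fit of all genes 334 of 965 differed between days, among them 150 of 279 small nucleolar RNA, 15 of 22 mitochondrial transfer RNA, 2 of 2 mitochondrial ribosomal RNA, 23 of 55 small nuclear RNA and 58 of 204 microRNA genes. Adjusted p is given for the 25 of these 334 that the naming rule had picked. Among small nucleolar RNAs it was, by edgeR, 6.81e-07 for SNORD5, 2.28e-06 for SNORD58A, 4.11e-06 for SNORD45B, 3.56e-05 for snoU2-30, 0.0025 for SNORD33 and 0.00337 for SNORA5C. SNORD70 had 0.0178, SNORD54 0.0196, SNORD68 0.0298, U8 0.0322 and SNORD92 0.0384. Among spliceosomal and 5S-related genes it was 0.0011 for RNVU1-7, 0.00812 for RNU5D-1, 0.0138 for RNA5SP207, 0.0178 for RNU2-6P, 0.0223 for RNU5F-1, 0.038 for RNA5SP199, 0.0404 for RNA5SP486 and 0.0439 for RNU5E-6P. The others of the 25 were RP5-875O13.1 (3.64e-06), RBMX (1.75e-05), LINC00623 (8.67e-05), TMC5 (0.00155) and the matrix genes COL1A1 (0.0024) and FN1 (0.00783).

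One library stood apart within its medium. The share of small Cajal body RNA, a class that guides modification of spliceosomal RNA, was 0.0510% in basal day 9 replicate 1, and the nearest basal library had 0.0617% (gap over range 0.793, against a limit of 0.625 for 6 libraries). It was 1 of 22 shares tested, and chance passes that limit in about 1 in 20.

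Division by medium gave more calls than other divisions of the libraries. The day-adjusted comparison called 36 microRNA genes, and the highest of the other splits gave 17, so that 1 of 100 drawn splits, the real one, gave as many. In the fit of all genes it called 94, the highest other split gave 16, and again 1 of 100 gave as many. Of the 99 other drawn splits 97 parted the 2 libraries of a group, which favours the real split wherever paired libraries are alike. The drawn splits therefore do not exclude chance, nor a difference that both libraries of a group share, such as 1 culture or preparation. Exchanging media over whole days, which keeps groups together, leaves 4 splits, too few for a share under 0.05; the highest other gave 0 for microRNA genes and 0 for all genes (edgeR).

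Small nucleolar RNA genes were higher in endothelial than in basal medium at day 9, with a median log2 fold change of 1.07. The median stayed at 0.97 (SE 0.101, 241 genes) after thinning every library to the shallowest, which argues against unequal counts alone. Thinning keeps the expected share of each gene, so it cannot test whether the make-up of a library changes with its yield. A difference in RNA or library quality carried by the basal day 9 libraries stays open and was not decided by any table: the higher of their 2 shares was 14.7%, while the lowest of the other 10 libraries had 26.7%, which restates the pattern. It cannot be told apart from a response to medium at day 9, because both rest on the same 2 libraries. The day 9 comparison of all genes may therefore partly reflect these libraries.

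MIR143 and MIR145, neighbours that share the host gene CARMN, were lower in endothelial medium at day 14. Scaling was argued against, since the log2 fold change nearest to 0 over 3 scalings was -1.12 (SE 0.0901). A smaller share of mesenchymal or smooth muscle-like cells stays open. The other 15 tested genes of that microRNA list went both ways (median 0.0480, SE 0.188, 8 higher and 7 lower). The summed stromal messenger RNAs were lower, at 537 ± 12.4 against 1146 ± 33.2 CPM of all counts (SD, n = 2). Most of that sum was COL1A1 (-1.18), with 739 of 1035 and 806 of 1075 counts in endothelial medium. In basal medium it had 1236 of 1513 and 876 of 1066, so sum and gene are not separate evidence. Summed pericyte and smooth muscle messenger RNAs overlapped between media, at 9.69 and 11.7 against 13.4 and 7.68 CPM of all counts. These rest on 7 to 23 counts per library. The pair did not always move together: at day 9 MIR143 stood at -1.07 and MIR145 at -0.39 (-0.06 with library sizes from all genes), and from day 3 to day 14 in basal medium MIR143 was higher by 0.73 and MIR145 lower at -0.40. Batch was not tested, as the labels give none, VEGF and serum differed together, and no biological explanation is put forward.

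Small nuclear RNA genes were lower in endothelial medium, and the deciding tests for this pattern were chosen, and those of scaling and length rewritten, after first outcomes had been seen. In its first form the scaling test was undecided, since 1 of 27 class-by-day ratios was not lower, and the length test had favoured selection by length, with SNORA genes below SNORD genes by a log2 difference of -0.31 (SE 0.147). In the rewritten tests the ratio was lower at day 14 against 8 of 9 other classes, which argues against growth of 1 other class, and at day 14 5 of 5 summed families from U1 to U6 were lower, which argues against reads moving between copies on that day; at day 9 U5 (log2 ratio -0.00) and U6 (0.23) were not lower. MicroRNA genes, the shortest, lay below SNORD genes by -0.59 (SE 0.0844), which argues against selection by length alone. A difference in library preparation between media may still account for the pattern, since the labels do not say how libraries were batched, and no biological explanation is put forward.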

How the results depend on the processing

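Leaving out the 4 day 9 libraries, thinning and the splits of the microRNA share within days were chosen after seeing the data; all other alternatives were fixed beforehand. Where 1 library was left out of a group, the remaining one was assumed to vary like the other groups. Depth limits what was called: at day 9 a 2-fold change of a microRNA gene was called in 57.1% of simulated cases.

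Counts of microRNA genes called stood at 0, 41, 37 and 36 (days 3, 9, 14 and day-adjusted). The DESeq2 Wald test gave 1 at day 3 and 17 for basal day 14 against day 3 (main 11). For the medium-by-day terms (main 15), DESeq2's likelihood-ratio test gave 25. That day's libraries alone gave 2 at day 3 and 11 at day 9, with fewer residual degrees of freedom. Library sizes from all genes gave 14 day-adjusted, 54 for the medium-by-day terms, 66 for basal day 9 (main 40), 17 for basal day 14 and 80 for endothelial day 14 (main 19). Summed copies gave 23 for the medium-by-day terms, 19 for basal day 14 and 34 for endothelial day 14. The mean of the 3 day contrasts gave 56. Without day 9 libraries, basal day 14 gave 19 and endothelial day 14 gave 33. For all genes, day 3 (main 2) gave 6 with no filter, 37 with DESeq2 and 0 with that day's libraries alone; the day-adjusted count (main 94) was 222 with DESeq2, 397 by the mean of contrasts and 59 without day 9 libraries. The count of lists called (main 1) was 0 with no filter, with an estimated correlation and without day 9 libraries. The cause was not tested for these shifts.

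The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated above 0.1 in 3 of 15 pairs of groups (median 0.02). With the number as a replicate block, all genes gave 0 at day 3 and 56 day-adjusted; every other count stayed within 1.5 times, with 41 microRNA genes at day 9, 38 at day 14 and 34 day-adjusted, and a microRNA share difference of -1.45.

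Leaving out each library in turn gave microRNA counts of 0 to 0 at day 3, 22 to 42 at day 9, 20 to 44 at day 14, 18 to 37 day-adjusted and 9 to 28 for the medium-by-day terms. Time comparisons gave 29 to 49 and 5 to 15 in basal, and 28 to 60 and 9 to 31 in endothelial medium, at days 9 and 14. All genes gave 0 to 4, 341 to 399, 113 to 260 and 16 to 160 (days 3, 9, 14 and day-adjusted). The list count was 1 to 1, and the microRNA share difference -2.12 to -0.70.

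One named gene changed sign: MIR210 at day 3 (main -0.09, never called) ran from -0.21 to 0.18 when libraries were left out, with 4 values above 0; the cause was not tested. For named genes, leaving out libraries kept direction and side of the threshold in 1813 cases, weakened 340, strengthened 3 and reversed 4. The other alternatives fixed beforehand kept 887, weakened 90 and strengthened 14; those added later kept 168, weakened 33 and strengthened 1. At day 14 MIR143, MIR145, MIR155, MIR20A, MIR30B, MIR126, MIR204 and MIR335 lost their call in none of their alternatives, and at day 9 neither did MIR143, MIRLET7B, MIR138-1, MIR138-2, MIR671 and MIR193A.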

Other observations

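The authors' tables and the time course of mitochondrial RNA are given as values; the test of neighbouring genes in this part was chosen after the data had been examined.

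Mitochondrial transfer RNAs, which serve translation inside mitochondria, differed between media in the fit of all genes, in a direction that depended on scaling at day 9. There edgeR called 16 of 22 higher and 1 lower in endothelial medium, yet their share of all counts was lower, 16.1% ± 0.231 against 18.5% ± 0.298 (SD, n = 2). At day 14 it called 14 higher and 0 lower, with shares of 8.64% ± 0.0405 and 7.09% ± 0.138; in the day-adjusted test 6 were higher and 0 lower. At day 3 edgeR called 0, and over the 3 days the share differed by -0.181 points (exact permutation p = 0.872). Both mitochondrial ribosomal RNAs were higher at day 9. The joint share of these RNAs at day 14 was 11.0% ± 0.0210 in endothelial and 9.19% ± 0.155 in basal medium (SD, n = 2), and at day 3 it was 8.52% ± 0.785 and 8.17% ± 0.319. Copies of these genes in the nucleus can share their reads.

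The authors' deposited tables, whose rows are mature microRNAs rather than genes, listed 6 of 336 at day 3, 59 of 249 at day 9 and 60 of 342 at day 14 with an adjusted p under 0.05. Matched by name to the microRNA genes, 239, 194 and 247 of their log2 fold changes correlated with those computed here with r of 0.716, 0.607 and 0.858 across genes, which are not independent replicates. Both come from the same libraries as far as the labels tell, so this is no independent evidence. The tables do not name a direction; a positive value was read as higher in endothelial medium because the signs then match, so the sign of these correlations shows nothing. At day 14 the authors' deposited table gave -1.56 for miR-143-3p, -1.24 for miR-145-5p, -1.45 for miR-155-5p, 3.57 for miR-126-3p, 3.07 for miR-204-5p and 1.60 for miR-335-5p. At day 3 the authors' deposited table passed miR-155-5p (-0.59), let-7a-2-3p (-0.81) and miR-199b-5p (0.78), with adjusted p of 0.0146, 0.0146 and 0.0203, where the count of calls here was 0. The smallest p of the authors' deposited day 9 table belonged to miR-3675-3p and miR-3675-5p, both at -3.51, yet the gene MIR3675 (hg38, chromosome 1, 16858949 to 16859021, -) had 0 counts in each of the 12 libraries, which allows up to 83.6 CPM in the shallowest. The authors' mean log2 CPM of both was 9.97 at day 9. That lies far above this level on the same scale, which argues against low depth as the reason.

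Neighbouring microRNA genes differed less in their change between media at day 14 than random pairs did. In 144 pairs within 10 kb on 1 strand, made of 102 genes, log2 fold changes differed by 0.470 on average, against 0.720 for random pairs (one-sided permutation p = 2e-04 from 100000 resamples). Shared primary transcripts are a candidate explanation, put forward as a hypothesis. Pairs that are copies of 1 microRNA can share reads, and that was not tested apart. Dense clusters give more pairs per gene, and unchanged genes differ little from each other. The DLK1-DIO3 cluster, with 26 tested genes, had 0 called at day 14 (median 0.095). Its part in this result was not tested.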
